A study of Mus musculus with 20 samples.

How the data were processed

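Gene expression was measured on 20 Agilent 1-colour mouse arrays of C2C12 cells, a mouse myoblast line that forms myotubes when serum is lowered. Per the labels' protocols, cells in 10% fetal bovine serum were transfected with 100 pmol of siRNA, moved 24 h later to 2% horse serum, and harvested after 24 h in that medium. Labelled RNA was made from 300 ng of total RNA. The labels give 5 groups of 4 arrays: a control siRNA (siControl), Six1 (siSix1), Six4 (siSix4), Six1 with Six4 (siSix1&4) and Myogenin (siMyogenin). The labels do not say whether the 4 replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

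The deposited scanner files hold spot intensity values on a linear scale, background-corrected by Agilent Feature Extraction 10.5.1.1 per the submitters' processing notes. The deposited series matrix holds log2 values, and its scale and centring are not stated in the sources used here. Recomputing it from the scanner files gave each value to within 0.0008: it is log2 of the median spot signal, minus each array's 75th percentile, minus each probe's median over the arrays, with higher values for brighter spots. Its column medians were -0.02, -0.50, -0.01 and 0.38 for siControl replicates 1 to 4, and -0.11, -0.45, -0.06 and 1.0 for siSix1. They were 0.15, -0.28, 0.03 and -0.09 for siSix4, 0.0, -0.32, 0.15 and 0.02 for siSix1&4, and -0.03, 0.49, 1.62 and 0.0 for siMyogenin.

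The values analysed were log2 of the processed signal minus each array's 75th percentile of it. Control spots were left out, as were spots with the scanner software's outlier marks, and spots of a probe were averaged. Each array held 43379 spots other than controls. Of 41174 probes, 24844 had 1 gene symbol in the files and 16330 had none, and the latter kept their accession or probe name. A probe was kept if it was well above background on all 4 arrays of at least 1 group, which left 22560 probes. The brightest kept probe stood for a gene. This gave 16902 genes, of which 11739 had a symbol and 4472 had several kept probes. No spot was saturated. The number of arrays limits the precision.

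The 75th percentile of the processed signal was 96.6 on siMyogenin replicate 3, 210.5 on siSix1 replicate 4, 382.8 on siMyogenin replicate 2 and 451.0 on siControl replicate 4. On the other arrays it was 625.6 to 1177.9. Between 44.3% and 75.4% of spots were well above background. Correlations between arrays of a group, taken across genes, which are not independent, were 0.941 to 0.996. The arrays lay on 5 slides scanned on 4 days per the file headers, slides 2 and 3 on the same day. Slides 1, 2 and 3 each held the same-numbered replicate of siControl, siSix1, siSix4 and siSix1&4. Slide 4 held siControl replicate 4 with siMyogenin replicates 1 to 3. Slide 5 held replicate 4 of siSix1, siSix4, siSix1&4 and siMyogenin, with no control.

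Groups were compared with limma 3.58.1 in R 4.3.3, in a group-means model over all 20 arrays with empirical Bayes moderation, and p-values were adjusted by the Benjamini-Hochberg method. A gene changed if its adjusted p was under 0.05. The 9 comparisons were each knockdown against siControl, siSix1&4 against siSix1, siSix4 and siMyogenin, siSix1 against siSix4, and the interaction of the Six1 and Six4 knockdowns. Changes are log2 differences with limma's standard error, and n is 4 arrays in each group. For a gene not well above background on any array of the dimmer group, a fold is given as "at least". It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal. Where only some arrays of the dimmer group measured a gene, their number is given, no fold is, and the log2 difference rests in part on signals not well above background. Data were read with Python 3.11.15, pandas 2.3.3 and, in R, data.table version 1.17.8, and drawn with matplotlib 3.10.9.

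The tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The naming rule took the 10 largest rises and 10 largest falls per knockdown, or 5 between knockdowns, among genes with symbols that passed and whose arrays did not overlap between the groups. It added up to 4 members of each list that passed and, in every comparison, Six1, Six4, Myog and 9 related regulators. Of 30 gene lists, 29 had at least 5 measured genes and were tested. The list of immune and endothelial markers had fewer and was not tested. Lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, and adjusted over the 29 lists.

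Replicate numbers pair the 4 groups other than siMyogenin: the deviations of same-numbered arrays from their group means correlated at 0.31 to 0.86 over 24 pairs (median 0.50). For siMyogenin with siSix1&4 they were 0.11, 0.25, 0.32 and 0.37 (-0.29 to 0.15 for different numbers), so by the limit of 0.1 these pair as well, though 3 of the 4 pairs lay on different slides. With siControl, siSix1 and siSix4 they were -0.24 to 0.44, with values under 0.1 in each, so there its numbers pair nothing. The slide was fitted as a block, and the replicate number as another. The self-test planted changes in values simulated for 16902 genes, with 50 genes at each fold. Without a block it recovered 86% of 4-fold and 32% of 2-fold changes for siSix1, 86% and 46% for siSix4, 90% and 46% for siSix1&4, and 90% and 32% for siMyogenin. False calls were 10 of 121, 7 of 124, 7 of 129 and 2 of 116 in the same order.

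The alternatives were quantile normalization, each array's median, normexp with an offset of 50, no filter, a filter on all arrays, spots with outlier marks kept, the mean of a gene's probes, the series matrix, only the arrays compared, array weights, a trended and robust fit, a 2-fold limit, the blocks, and each array left out in turn. Normexp used the median spot signal, because the files lack the mean signal. The slide as a random block, slides 1 to 3 alone, and leaving out siSix1 replicate 4 with siMyogenin replicate 3 were chosen after the data were seen, as were leaving out pairs of siMyogenin arrays, the lists with the replicate block and the simulations on the real slides. These gave each gene a shift per slide with the correlation of 0.33 estimated within slides.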

Results

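Transcript levels were measured on 20 arrays of C2C12 myoblasts after 24 h in differentiation medium. The 5 groups of 4 arrays received a control siRNA or siRNA against Six1, Six4, Six1 with Six4, or Myogenin. Six1 and Six4 are homeodomain transcription factors of the muscle lineage, and Myogenin (Myog) is a basic helix-loop-helix factor that drives terminal differentiation. The series asks how losing each factor changes gene expression early in differentiation. The 75th percentile of the signal was 96.6 on siMyogenin replicate 3, 210.5 on the array labelled siSix1 replicate 4, 382.8 on siMyogenin replicate 2 and 451.0 on siControl replicate 4, and 625.6 to 1177.9 on the others. The number of arrays limits the precision. Changes below are log2 differences with limma's SE and adjusted p, n = 4 per group, and a gene counts as measured on an array where its probe was well above background.

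Six1, on the log2 scale above each array's 75th percentile, stood at 4.11, 3.57, 3.89 and 4.45 on siControl replicates 1 to 4. It stood at 2.59, 2.46, 2.07 and 3.83 on siSix1 and at 2.91, 2.80, 2.44 and 3.43 on siSix1&4. The array labelled siSix1 replicate 4 goes against its label, with Six1 within the control range. Six1 fell in siSix1 (-1.27 ± 0.30, 2.41-fold, adjusted p = 0.017) and in siSix1&4 (-1.11 ± 0.30, 2.16-fold, adjusted p = 0.037). It stood at 4.57, 3.99, 4.21 and 4.53 in siSix4 (0.32 ± 0.30, adjusted p = 0.9) and at 4.68, 4.88, 4.87 and 4.78 in siMyogenin (0.80 ± 0.30, adjusted p = 0.087). A dimmer Six1 probe differed by -0.83 in siSix1 and -0.93 in siSix1&4. With the slide as a block the changes were -1.29, adjusted p = 0.0012 in siSix1 and -1.13, adjusted p = 0.0023 in siSix1&4. The siSix1 call was lost on leaving out any 1 of siControl replicate 1 (-1.23, adjusted p = 0.057), siControl replicate 4 (-1.12, adjusted p = 0.068) and siSix1 replicate 3 (-1.04, adjusted p = 0.079). The siSix1&4 call was lost on leaving out any 1 of siControl replicate 1 (-1.08, adjusted p = 0.1), siControl replicate 3 (-1.15, adjusted p = 0.069), siControl replicate 4 (-0.96, adjusted p = 0.12), siSix1&4 replicate 1 (-1.12, adjusted p = 0.075), siSix1&4 replicate 2 (-1.08, adjusted p = 0.088) and siSix1&4 replicate 3 (-0.96, adjusted p = 0.15).

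Six4 stood at -0.24, -0.23, -0.61 and -0.42 on siControl and at -1.30, -1.27, -1.59 and -2.18 on siSix4, below every control array. Its difference did not pass over all genes (-1.21 ± 0.44, adjusted p = 0.28), nor with the slide block (-1.0, adjusted p = 0.11), and passed with the replicate number as a block (-1.21, adjusted p = 0.046). It stood at -0.67, -0.84, -1.15 and -1.84 in siSix1&4 (-0.75 ± 0.44, adjusted p = 0.5) and at -0.36, -0.80, -1.74 and -1.42 in siMyogenin (-0.70 ± 0.44, adjusted p = 0.28). In siSix1 it stood at -0.05, -0.09, -0.34 and -2.47, the last on the array labelled siSix1 replicate 4 (-0.36 ± 0.44, adjusted p = 0.78).

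Myog stood at 7.40, 6.98, 7.17 and 7.74 on siControl and at 4.28, 5.68, 5.48 and 3.62 on siMyogenin, where it fell (-2.56 ± 0.68, 5.89-fold, adjusted p = 0.028). The slide-block change was -2.07, adjusted p = 0.035. That call was lost on leaving out any 1 of siControl replicate 1 (-2.53, adjusted p = 0.077), siControl replicate 2 (-2.67, adjusted p = 0.078), siControl replicate 3 (-2.61, adjusted p = 0.063) and siMyogenin replicate 4 (-2.18, adjusted p = 0.069). Myog also fell in siSix1&4, to 5.76, 5.20, 4.61 and 2.38 (-2.84 ± 0.68, 7.15-fold, adjusted p = 0.019). That call was lost on leaving out any 1 of siControl replicate 1 (-2.81, adjusted p = 0.056), siControl replicate 4 (-2.70, adjusted p = 0.061), siSix1&4 replicate 3 (-2.88, adjusted p = 0.053) and siSix1&4 replicate 4 (-2.14, adjusted p = 0.074). In siSix1, at 5.93, 5.57, 4.85 and 4.44, Myog did not pass (-2.13 ± 0.68, adjusted p = 0.084) but passed with the slide block (-1.62, adjusted p = 0.015), and the last value is from the array labelled siSix1 replicate 4. In siSix4, at 6.59, 6.12, 5.88 and 3.47, it passed neither way (-1.81 ± 0.68, adjusted p = 0.31, and -1.30, adjusted p = 0.092 with the block).

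**Figure D1:**
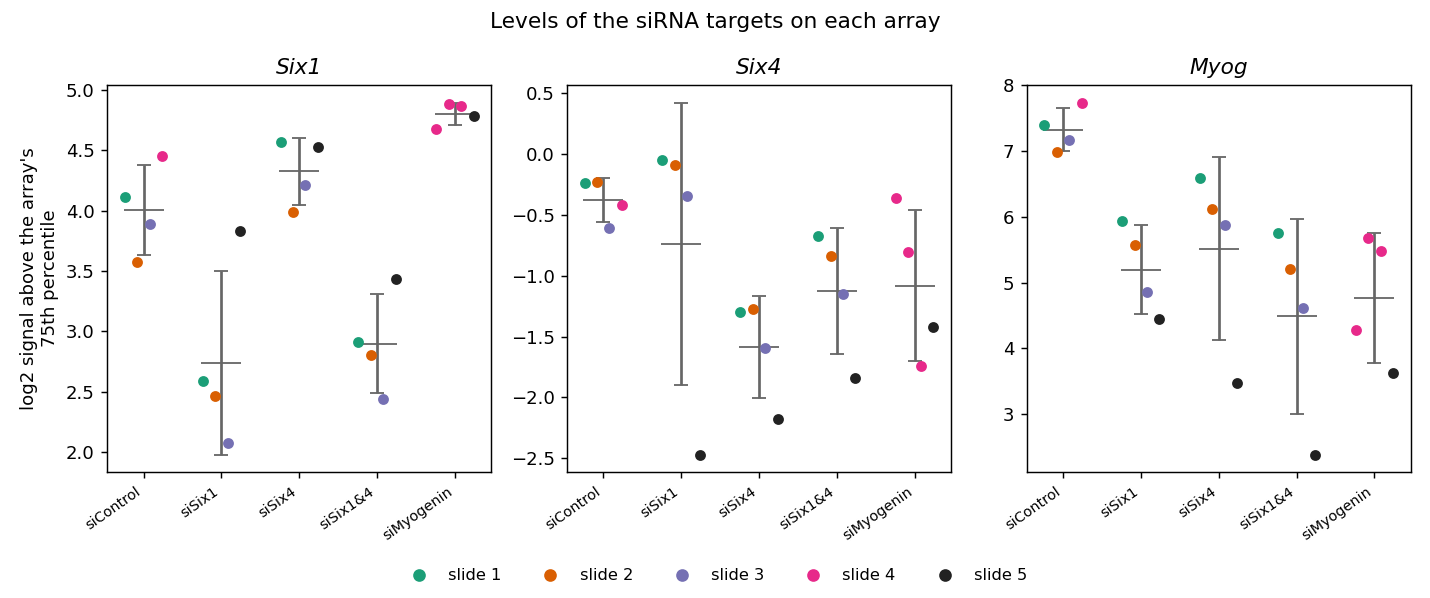
Log2 signal of Six1, Six4 and Myog above each array's 75th percentile on each of the 20 arrays. Six1 on the array labelled siSix1 replicate 4 (3.83) lies within the control range of 3.57 to 4.45, and Myog lies below the control arrays in each knockdown.

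Of 44 measured sarcomere genes in siSix1 9 fell, none rose and 35 did not pass, and 37 fell adjusted over the list alone. Those that fell included Tmod1, which caps thin filaments (-2.77 ± 0.46, adjusted p = 0.0015), the myosin light chain Myl1 (-2.47 ± 0.57, adjusted p = 0.015) and Nrap, a scaffold of myofibril assembly (-2.42 ± 0.55, adjusted p = 0.014). The list's mean change was -2.12 (SD 0.86 over genes), and its camera adjusted p of 7.1e-25 became adjusted p = 0.12 with an estimated correlation. Under the slide block 36 members fell and the mean was -1.76, and within slides 1, 2 and 3 it was -1.47, -1.44 and -2.23. Of 16 fast-fibre genes 5 fell, and 14 fell adjusted over the list alone (adjusted p = 0.058 with an estimated correlation, mean -2.31, and -1.98 with the slide block). They included the fast alpha-actinin Actn3 (-1.60 ± 0.24, adjusted p = 7.1e-04) and the calcium buffer Pvalb (at least 3.13-fold lower, adjusted p = 0.0064, not measured on any siSix1 array). Of 10 slow-fibre genes 2 fell, the troponin Tnnt1 (-1.27 ± 0.28, adjusted p = 0.011) and the myosin light chain Myl3 (-2.72 ± 0.61, adjusted p = 0.012), whose other probe showed 0.50. Adjusted over the list alone 9 slow-fibre genes fell and 1 rose (adjusted p = 0.19 with an estimated correlation). None of 9 embryonic and cardiac isoforms passed, and 6 fell adjusted over the list alone (mean -1.65, adjusted p = 0.19 with an estimated correlation).

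Of 18 excitation-contraction genes in siSix1 8 fell and none rose, and 14 fell adjusted over the list alone, including the calcium channel Cacna1s (-2.94 ± 0.79, adjusted p = 0.035) and the release channel Ryr1 (-2.92 ± 0.79, adjusted p = 0.035). Of 10 neuromuscular junction genes 3 fell: Dok7, which activates the receptor kinase MuSK (-1.87 ± 0.30, adjusted p = 0.0013), and the acetylcholine receptor subunits Chrng (-1.75 ± 0.34, adjusted p = 0.0056) and Chrnd (-1.19 ± 0.25, adjusted p = 0.0084). Of 16 muscle metabolism genes 6 fell, including the glycogen phosphorylase Pygm (-2.81 ± 0.60, adjusted p = 0.0098, measured on 3 of 4 siSix1 arrays) and the glycolytic enzyme Pgam2 (-2.59 ± 0.56, adjusted p = 0.011), while Cox8b passed without the block only (-1.76 ± 0.48, adjusted p = 0.037, slide block -1.59 and adjusted p = 0.055). Of 15 dystrophin-complex genes the sarcoglycans Sgcg (-2.32 ± 0.27, adjusted p = 1.3e-04) and Sgca (-1.43 ± 0.18, adjusted p = 1.5e-04) fell. Of 5 adipocyte markers the lipoprotein lipase Lpl (-1.94 ± 0.22, adjusted p = 6.7e-05), the fatty acid transporter Cd36 (-2.99 ± 0.49, adjusted p = 0.0013, measured on 1 of 4 siSix1 arrays) and the transcription factor Cebpa (-0.97 ± 0.19, adjusted p = 0.005) fell. Lpl and Cd36 are also expressed in muscle. The means of these 5 lists were -1.79, -0.77, -1.35, -0.52 and -1.54, and -1.57, -0.75, -1.18, -0.53 and -1.37 with the slide block. Without a block their camera calls hold with an estimated correlation, at adjusted p of 0.048, 0.027, 0.027, 0.016 and 0.016. With the slide block these became 0.046, 0.067, 0.067, 0.046 and 0.046, and with the replicate block 0.052, 0.076, 0.076, 0.052 and 0.052, so that none of the 5 passed under the latter. Within slides 1, 2 and 3 the excitation-contraction mean was -1.47, -1.38 and -1.76 and the adipocyte mean -1.54, -1.17 and -1.88.

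Among 18 myogenic regulators Myod1, which commits cells to the muscle lineage, fell in siSix1 (-1.38 ± 0.25, adjusted p = 0.0036). Mef2a fell (-0.71 ± 0.20, adjusted p = 0.04) and the repressor Bhlhe40 rose (0.98 ± 0.21, adjusted p = 0.01), and the list had a mean of -0.41 (adjusted p = 0.12 with an estimated correlation). Myf5 (0.58 ± 0.83, adjusted p = 0.82) and Mef2c (-2.09 ± 0.95, adjusted p = 0.27) did not pass. Myf6 (-0.82 ± 0.26, adjusted p = 0.083) and Eya1 (0.59 ± 0.23, adjusted p = 0.17) passed with the slide block (-0.67, adjusted p = 0.027, and 0.60, adjusted p = 0.023), and with the replicate block Myf6 (-0.82, adjusted p = 0.0027) and Mef2c did (-2.09, adjusted p = 0.042). Of 11 cell cycle exit genes the kinase inhibitors Cdkn1c and Cdkn1a, the retinoblastoma gene Rb1 and the cyclin Ccnd3 fell (-1.79, -1.03, -1.05 and -0.94, list adjusted p = 0.38 with an estimated correlation). Of 11 insulin-like growth factor genes Igf2 (-3.15 ± 0.74, adjusted p = 0.016) and Igf1 (-1.14 ± 0.24, adjusted p = 0.0078) fell. The largest fitted rises included Calcb, a calcitonin gene-related peptide (at least 5.7-fold higher, adjusted p = 1.1e-04, not measured on any siControl array), the Rho GTPase-activating protein Arhgap6 (3.46 ± 0.37, adjusted p = 5.3e-05, measured on 2 of 4 siControl arrays), the chemokine receptor Cxcr6 (3.12 ± 0.38, adjusted p = 1.5e-04) and the interleukin-1 receptor antagonist Il1rn (2.41 ± 0.22, adjusted p = 1.4e-05). The largest fitted falls included the ferritin receptor Scara5 (-3.99 ± 0.40, adjusted p = 3.4e-05, measured on 1 of 4 siSix1 arrays) and the BMP co-receptor Hjv (-3.74 ± 0.84, adjusted p = 0.013, measured on 3 of 4 siSix1 arrays).

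In siSix1, of 17 fusion genes the membrane repair gene Dysf and the cadherin Cdh15 fell (-1.12 and -0.74). Of 26 extracellular matrix genes Tnc and the protease Mmp14 rose (1.54 and 1.0). Of 21 interferon-response GTPases and related genes Igtp fell and Irgm1 rose (-1.63 and 0.92). Of 16 inflammatory genes the chemokines Cxcl5 and Cxcl1 fell (-2.46 and -1.08), as did the acute-phase gene Saa3 (-2.14 ± 0.55, adjusted p = 0.029, measured on 1 of 4 siSix1 arrays), and Ptgs2 rose (0.87). The Notch effector Heyl fell (-1.80), the only 1 of 12 Notch genes to pass, and 1 of 13 progenitor genes fell. Pcsk9, which degrades the LDL receptor, rose among 23 cholesterol genes (1.54), and Asns fell among 23 unfolded-protein genes (-1.44). No gene passed among 31 mitosis (mean 0.02), 34 DNA replication (-0.14, adjusted p = 0.61 with an estimated correlation), 27 oxidative phosphorylation (-0.22, adjusted p = 0.61 with an estimated correlation) and 32 ribosomal protein genes (0.11). None passed among 15 cytoskeletal, 16 p53 target, 9 osteoblast and chondrocyte, 7 neural and 5 Eya, Pax7 and Six5 genes.

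In siSix1 842 of 16902 genes changed, 397 higher and 445 lower, and 513 by at least 2-fold. In the slide-block fit 1549 changed, and with the replicate block 1583. With the latter 6 regulator, 38 sarcomere, 13 fast-fibre, 9 slow-fibre, 6 embryonic and cardiac, 14 excitation-contraction and 5 junction genes fell. Scaling to each array's median gave 199 higher and 423 lower. The count was 163 under normexp, 366 with no filter, 491 from the series matrix, 524 from only the arrays compared and 4987 with array weights. Arrays left out 1 at a time, here and below, gave 439 and 503 without siControl replicates 1 and 4, and 431 without siSix1 replicate 3, and 764 without the array labelled siSix1 replicate 4. That array is among the 4 siSix1 arrays in every direction given. Of 64 named genes that passed, 39 did so whichever array was left out, among them Actn3, Cxcr6, Dok7, Lpl, Myod1, Sgca, Sgcg and Tmod1.

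Fewer genes changed in siSix4. Areg, a ligand of the epidermal growth factor receptor, rose (2.18 ± 0.26, 4.53-fold, adjusted p = 0.002), as did Arhgap6 (2.73 ± 0.37, adjusted p = 0.0028, measured on 2 of 4 siControl arrays), the membrane protein gene Lrrn4cl (1.99 ± 0.32, adjusted p = 0.0068) and the cytochrome Cyb561 (1.56 ± 0.22, adjusted p = 0.0032). Plagl1, a zinc finger transcription factor, showed the largest fall of those named by the rule (-3.00 ± 0.53, 8.03-fold, adjusted p = 0.015). The glutathione transferases Gsta2 (-2.60 ± 0.41, adjusted p = 0.0058, measured on 3 of 4 siSix4 arrays) and Gsta1 (-2.39 ± 0.47, adjusted p = 0.029) fell, as did the proline-rich protein gene Prr9 (at least 2.68-fold lower, adjusted p = 0.0032, not measured on any siSix4 array). Of 44 sarcomere genes none passed, and 2 fell adjusted over the list alone. Their mean of -1.13 (SD 0.67) had a camera adjusted p of 2.0e-12 but adjusted p = 0.35 with an estimated correlation. With the slide block 4 fell and the mean was -0.77, and within slides 1, 2 and 3 it was -0.65, -0.30 and -0.70. Of 18 excitation-contraction genes the cation channel Tmem38a fell (-1.46 ± 0.31, adjusted p = 0.041, list adjusted p = 0.13 with an estimated correlation). Of 11 cell cycle exit genes Cdkn1c fell (-2.19 ± 0.45, adjusted p = 0.035, list adjusted p = 0.36 with an estimated correlation). Zmat3, an RNA-binding protein gene induced by p53, rose (0.96 ± 0.16, adjusted p = 0.0068), the only 1 of 16 p53 targets to pass (list adjusted p = 0.21 with an estimated correlation).

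The 31 mitosis genes were higher in siSix4 as a list (mean 0.59, SD 0.22, camera adjusted p = 1.3e-15), with none called over all genes and 7 higher adjusted over the list alone. The list had adjusted p = 0.094 with an estimated correlation. Within slides 1, 2 and 3 their mean was 0.91, 0.58 and 0.66, and with the slide block it was 0.60 and 2 rose. Myod1 (-0.65 ± 0.25, adjusted p = 0.34), Myf5 (1.07 ± 0.83, adjusted p = 0.83) and Mef2c (-0.64 ± 0.95, adjusted p = 0.96) did not pass, and Eya1 passed with the slide block (0.78, adjusted p = 0.014) and the replicate block (0.77, adjusted p = 0.032). In siSix4 74 genes changed, 32 higher and 42 lower, against 447 with the slide block and 483 with the replicate block. Scaling to each array's median gave 18 higher and 48 lower, a filter on all arrays 31 higher and 27 lower, no filter 9 higher and 7 lower, and normexp 5 higher and 1 lower. The count was 227 with quantile normalization, 31 from the series matrix, 256 from only the arrays compared and 4697 with array weights. Singly left out, arrays gave 16, 26, 23 and 29 without siControl replicates 1, 2, 3 and 4, and 43, 33, 20 and 27 without siSix4 replicates 1, 2, 3 and 4. With the replicate block 3 regulator, 4 sarcomere, 3 fast-fibre and 3 excitation-contraction genes fell and 3 mitosis and 1 neural genes rose. Of 22 named genes that passed, 9 did so whichever array was left out, among them Areg, Arhgap6, Cyb561, Gsta2, Prr9 and Zmat3. Without a block no camera call of a list in siSix4 holds with an estimated correlation, and with the slide block that of the neural list does (mean 0.70, adjusted p = 0.048, and 0.25 with the replicate block).

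Of 44 sarcomere genes in siSix1&4 23 fell and none rose, and 41 fell adjusted over the list alone. They included Csrp3, the muscle LIM protein (-3.77 ± 0.95, adjusted p = 0.025), the thin-filament gene Neb (-3.75 ± 0.99, adjusted p = 0.033, measured on 3 of 4 siSix1&4 arrays), the myosin chaperone Unc45b (-3.56 ± 0.96, adjusted p = 0.037) and the fast troponin Tnnt3 (-3.39 ± 0.87, adjusted p = 0.028). The mean was -2.51 (SD 1.01), with a camera adjusted p of 2.2e-33 and adjusted p = 0.054 with an estimated correlation. Once the slide was a block, 38 fell, the mean was -2.16 and that p was 0.047. Within slides 1, 2 and 3 the mean was -1.81, -1.82 and -2.33. Of 16 fast-fibre genes 11 fell, including the calcium pump Atp2a1 (-3.76 ± 1.02, adjusted p = 0.038) and Pvalb (at least 3.42-fold lower, adjusted p = 0.0056, not measured on any siSix1&4 array). Of 10 slow-fibre genes 3 fell (adjusted p = 0.12 with an estimated correlation), including the troponin Tnnc1 (-3.02 ± 0.78, adjusted p = 0.028) and Myl3 (-2.71 ± 0.61, adjusted p = 0.013), whose other probe showed 0.41. Of 9 embryonic and cardiac isoforms 2 fell (adjusted p = 0.13 with an estimated correlation). Of 18 excitation-contraction genes 10 fell, including the calcium-binding protein Hrc (-3.31 ± 0.78, adjusted p = 0.017), and of 16 metabolism genes 6 fell, including the creatine kinase Ckm (-3.48 ± 0.96, adjusted p = 0.041). Of 10 junction genes 3 fell, including Chrng (-1.87 ± 0.34, adjusted p = 0.0039), and of 17 fusion genes 4 fell, including Mymk, which is needed for myoblast fusion (-3.11 ± 0.75, adjusted p = 0.02). The fusion list had a mean of -0.40 and a median of 0.02.

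Of 18 myogenic regulators 4 fell in siSix1&4, 1 rose and 13 did not pass (adjusted p = 0.031 with an estimated correlation). Tead4 (-2.40 ± 0.60, adjusted p = 0.025), Myod1 (-1.20 ± 0.25, adjusted p = 0.0089), Hes6 (-1.06 ± 0.25, adjusted p = 0.019) and Mef2a (-0.73, adjusted p = 0.035) fell, and Bhlhe40 rose (0.87 ± 0.21, adjusted p = 0.021). Mef2c (-2.41 ± 0.95, adjusted p = 0.2) and Eya1 (0.78 ± 0.23, adjusted p = 0.06) passed with the slide block (-1.63, adjusted p = 0.04, and 0.79, adjusted p = 0.0042) and the replicate block (-2.41, adjusted p = 0.021, and 0.78, adjusted p = 0.011). Sgcg, Sgca, Lpl, Cebpa, Igf2 and Igf1 fell in siSix1&4 too (-2.36, -1.27, -1.23, -0.76, -3.23 and -0.94), and so did Cd36 (-2.53 ± 0.49, adjusted p = 0.0048, measured on 1 of 4 siSix1&4 arrays). Cdkn1c, Cdkn1a, Ccnd3 and Rb1 fell among 11 cell cycle exit genes (-2.30, -1.24, -1.03 and -0.91, list adjusted p = 0.18 with an estimated correlation). The 31 mitosis genes had a mean of 0.25 with none called (adjusted p = 0.52 with an estimated correlation), and the 27 oxidative phosphorylation genes a mean of -0.18 (adjusted p = 0.71 with an estimated correlation). Calcb (at least 5.18-fold higher, adjusted p = 1.5e-04, not measured on any siControl array), Arhgap6 (3.79 ± 0.37, adjusted p = 2.8e-05, measured on 2 of 4 siControl arrays), Cxcr6 (3.26 ± 0.38, adjusted p = 1.2e-04) and the peptide hormone Cck (3.02 ± 0.46, adjusted p = 0.001, measured on 3 of 4 siControl arrays) rose. The ADP-ribosyltransferase Art1 (-4.49 ± 0.86, adjusted p = 0.0047, measured on 2 of 4 siSix1&4 arrays) and the muscle kinase Srpk3 (-4.03 ± 0.95, adjusted p = 0.017) fell. The stem cell receptor Lgr5 rose without the block only (2.79 ± 0.72, adjusted p = 0.028, measured on 3 of 4 siControl arrays, slide block 2.22 and adjusted p = 0.055).

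Without a block camera calls in siSix1&4 hold with an estimated correlation for 7 lists: regulators, fast fibre, excitation-contraction, junction, metabolism, dystrophin complex and adipocyte, at adjusted p of 0.031, 0.027, 0.027, 0.027, 0.024, 0.019 and 0.022. With the slide block these became 0.064, 0.047, 0.028, 0.051, 0.05, 0.028 and 0.048, and with the replicate block 0.052, 0.052, 0.05, 0.07, 0.052, 0.041 and 0.052. Their means were -0.50, -2.67, -2.00, -0.71, -1.49, -0.53 and -1.28, and -0.45, -2.35, -1.78, -0.68, -1.32, -0.54 and -1.1 with the slide block. In siSix1&4 824 genes changed, 364 higher and 460 lower, against 1451 with the slide block and 1427 with the replicate block. Scaling to each array's median gave 182 higher and 424 lower. With the replicate block 41 sarcomere, 9 slow-fibre and 7 embryonic and cardiac genes fell. The count was 243 under normexp, 350 with no filter and 3695 with array weights, and 448, 544 and 528 without siControl replicates 1, 2 and 4, and 403 and 482 without siSix1&4 replicates 3 and 4. Of 65 named genes that passed, 31 did so whichever array was left out, among them Art1, Calcb, Cck, Cxcr6, Myod1, Pygm, Sgca and Sgcg.

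**Figure D2:**
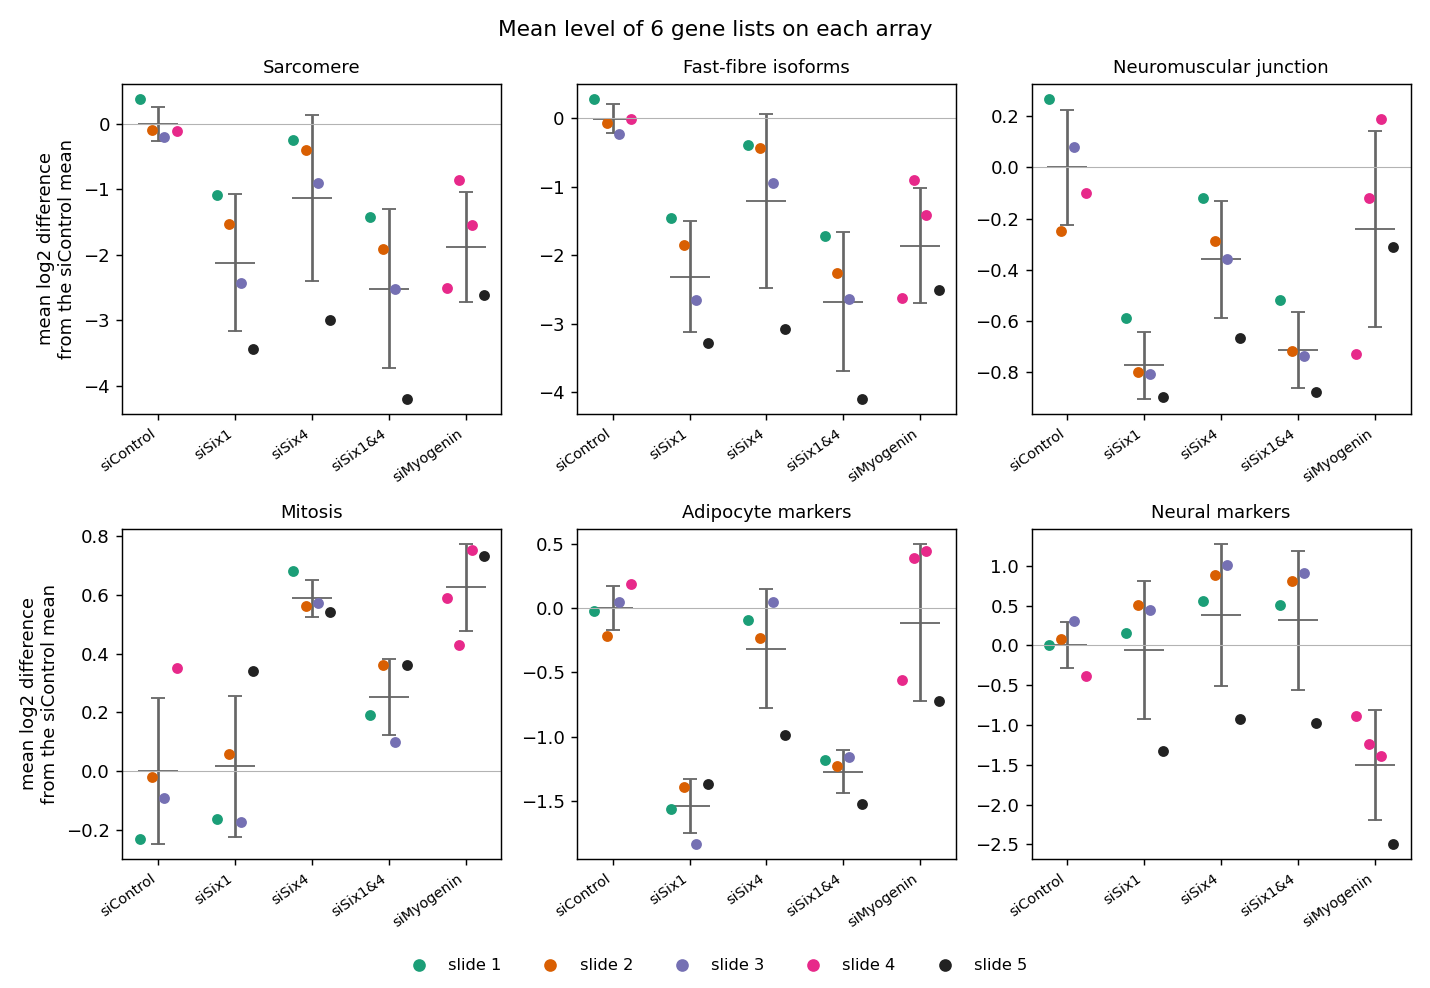
Mean level of 6 gene lists on each array relative to the control mean, coloured by slide, with group mean and SD (n = 4). The sarcomere list lies lowest on replicate 4 of siSix1, siSix4 and siSix1&4, which share slide 5.

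In siMyogenin the myosin heavy chains Myh4 (-4.40 ± 0.96, adjusted p = 0.014, measured on 3 of 4 siMyogenin arrays) and Myh1 (-3.85 ± 0.98, adjusted p = 0.024) and Neb (-3.82 ± 0.99, adjusted p = 0.026) fell, and did so with the slide block (-2.59, adjusted p = 0.015, -1.94, adjusted p = 0.04, and -2.22, adjusted p = 0.018). Myh2 fell without the block only (at least 18.8-fold lower, adjusted p = 0.024, not measured on any siMyogenin array, slide block -1.89 and adjusted p = 0.084), and its other probes showed -1.51 and -1.41. Of 44 sarcomere genes 13 fell and none rose, and 26 fell adjusted over the list alone. Their mean was -1.88 (SD 1.33, camera adjusted p = 2.7e-12, adjusted p = 0.44 with an estimated correlation). When blocked by slide, 6 fell and the mean was -1.09, and on slide 4 it was -1.53. Of 16 fast-fibre genes 4 fell (mean -1.86, and -1.19 with the slide block, adjusted p = 0.44 with an estimated correlation). Of 10 slow-fibre genes 1 fell (adjusted p = 0.56 with an estimated correlation). Of 9 embryonic and cardiac isoforms 3 fell, including Myl4 (-3.30 ± 0.88, adjusted p = 0.028), and the list had adjusted p = 0.43 with an estimated correlation. Of 18 excitation-contraction genes 2 fell (adjusted p = 0.43 with an estimated correlation), including the calcium store protein Casq2 (-3.86 ± 1.12, adjusted p = 0.038). Tead4 fell (-2.62 ± 0.60, adjusted p = 0.017), and with the slide block as well (-1.81, adjusted p = 0.0073). The fusion gene Mymk fell without the block only (-2.46 ± 0.75, adjusted p = 0.046, slide block -1.44 and adjusted p = 0.1), and Myod1 (-0.50 ± 0.25, adjusted p = 0.19) and Mef2c (-2.08 ± 0.95, adjusted p = 0.15) did not pass. The metabolism list (3 of 16 fell) had adjusted p = 0.47 with an estimated correlation, and the dystrophin list (1 of 15) 0.43.

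Among the largest fitted rises in siMyogenin, the succinate receptor Sucnr1 (4.28 ± 0.62, adjusted p = 0.0022, measured on 2 of 4 siControl arrays), the protease inhibitors Csta2 (3.96 ± 0.50, adjusted p = 7.8e-04) and Csta1 (3.93 ± 0.54, adjusted p = 0.0016), the chemokine Cxcl13 (3.45 ± 0.74, adjusted p = 0.014) and the secreted chaperone Clu (2.22 ± 0.31, adjusted p = 0.0016) also passed with the slide block (3.61, 3.36, 3.17, 3.49 and 2.29). Zmat3 rose (0.99 ± 0.16, adjusted p = 0.0034), as it did with the block (1.17, adjusted p = 0.0039). Of 31 mitosis genes 13 rose and none fell, and 16 rose adjusted over the list alone. They included the centromere histone Cenpa (1.64 ± 0.40, adjusted p = 0.021, slide block 0.93 and adjusted p = 0.31), the survivin gene Birc5 (1.54 ± 0.38, adjusted p = 0.022, slide block 0.69 and adjusted p = 0.4) and the anaphase activator Cdc20 (1.51 ± 0.39, adjusted p = 0.025, slide block 0.73 and adjusted p = 0.43). Their mean was 0.63 (SD 0.52, camera adjusted p = 2.2e-06, adjusted p = 0.43 with an estimated correlation). With the slide block 0 passed and the mean was 0.43, and on slide 4 it was 0.24. Of 34 DNA replication genes 9 rose (adjusted p = 0.44 with an estimated correlation), including the thymidylate synthase Tyms (1.19 ± 0.29, adjusted p = 0.021, slide block 0.60 and adjusted p = 0.41), and 1 rose with the slide block. Of 23 cholesterol genes 4 rose (adjusted p = 0.68 with an estimated correlation), including the receptor Ldlr (1.41 ± 0.34, adjusted p = 0.021, slide block 0.79 and adjusted p = 0.064). The 32 ribosomal protein genes (adjusted p = 0.72 with an estimated correlation) and 27 oxidative phosphorylation genes (adjusted p = 0.7 with an estimated correlation) had means of 0.43 and 0.39, but -0.02 and 0.05 with the slide block. Of 21 interferon-response, 16 inflammatory and 11 insulin-like growth factor genes 4, 3 and 3 rose, and none of these passed with the slide block. Of 11 cell cycle exit genes Cdkn1c (-1.46 ± 0.45, adjusted p = 0.046, slide block -0.99 and adjusted p = 0.17) and Cdkn1a (-0.93 ± 0.26, adjusted p = 0.033, slide block -1.02 and adjusted p = 0.15) fell without the block only, and the list had a mean of 0.01 and a median of -0.09. Eya1, a partner of Six1, rose without the block only (1.03 ± 0.23, adjusted p = 0.016, slide block 0.57 and adjusted p = 0.15). Probes disagreed for Ablim3 (-4.21 against 0.11) and Col5a1 (0.52 against -0.68).

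In siMyogenin 1724 genes changed, 1016 higher and 708 lower. Blocking by slide, 231 did, 96 higher and 135 lower, of which 201 were among the 1724. Each array's median gave 1817 higher and 441 lower, a filter on all arrays 1152 higher and 492 lower, the series matrix 523 higher and 194 lower, no filter 76 higher and 82 lower, and normexp 35 higher and 40 lower. The median change of all genes was 0.05, and 0.30, 0.15, 0.23, 0.26 and 0.28 under these in turn. The count was 718 from only the arrays compared and 6493 with array weights, and 240, 200, 475 and 2998 without siControl replicates 1, 2, 3 and 4, and 822, 795 and 1045 without siMyogenin replicates 2, 3 and 4. Without both siMyogenin replicates 2 and 3, the arrays of that group with the lowest signal, 412 genes changed, and 676 with the slide block. Of 75 named genes that passed, 14 did so whichever array was left out, among them Csta1, Csta2, Cxcl13, Clu, Sucnr1 and Zmat3. No camera call of a list in siMyogenin holds with an estimated correlation.

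**Figure D3:**
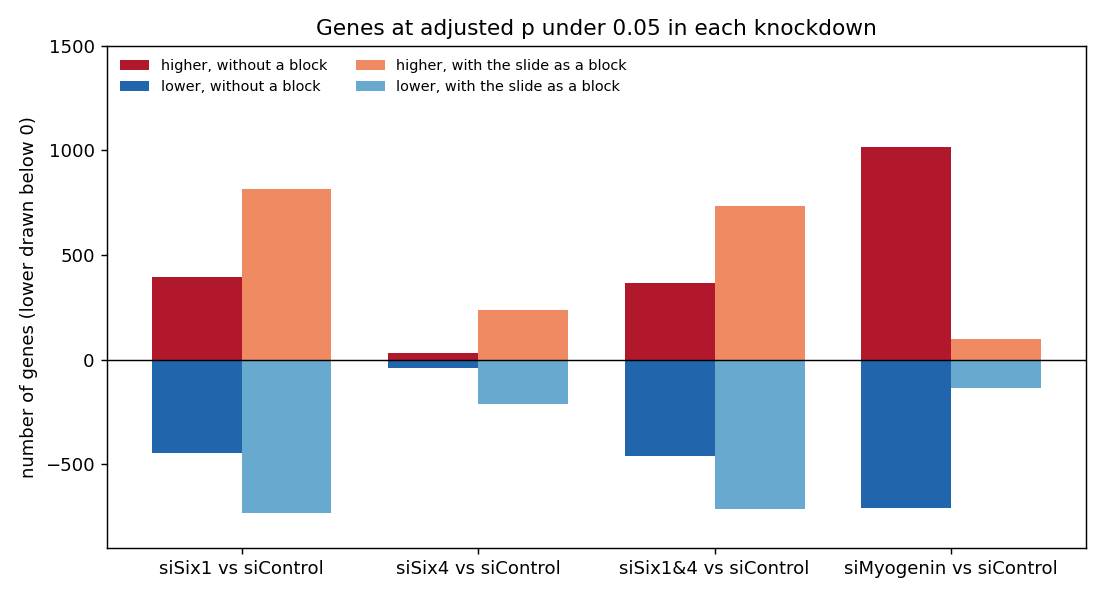
Number of genes at adjusted p under 0.05 in each knockdown against siControl, higher above 0 and lower below it, without a block and with the slide as a block. The siMyogenin count went from 1724 to 231, and the siSix1 count from 842 to 1549.

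Whether losing Six4 adds to losing Six1 was asked by siSix1&4 against siSix1, with the array labelled siSix1 replicate 4. The 44 sarcomere genes had a mean of -0.40 (SD 0.30), with none called (adjusted p = 0.83 with an estimated correlation). Within slides 1, 2, 3 and 5 that mean was -0.34, -0.38, -0.10 and -0.76. Myog (-0.71 ± 0.68), Six1 (0.16 ± 0.30) and Six4 (-0.38 ± 0.44) did not pass (all adjusted p = 1). Six4 was lower on slides 1 to 3 only, so few calls leave the question open. The 31 mitosis genes had a mean of 0.23 (camera adjusted p = 3.1e-07, adjusted p = 0.49 with an estimated correlation). The 7 neural genes had a mean of 0.37 (adjusted p = 0.83 with an estimated correlation, 0.049 with the slide block and 0.49 with the replicate block), with none called and 0.36, 0.30, 0.46 and 0.35 within those slides. limma called 0 genes with no block, the slide block and the replicate block, and 245, 728 and 550 had an unadjusted p under 0.05. Array weights called 5, and slides 1 to 3 with the slide block 34.

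Whether losing Six1 adds to the loss of Six4 was asked by setting siSix1&4 against siSix4. Six1 was lower (-1.43 ± 0.30, adjusted p = 0.049). Lpl (-2.13 ± 0.22, adjusted p = 1.4e-04), Scara5 (-2.75 ± 0.40, adjusted p = 0.0031, measured on 2 of 4 siSix1&4 arrays), Cxcl13 (-3.64 ± 0.74, adjusted p = 0.039, measured on 2 of 4 siSix1&4 arrays) and Cxcl5 (-1.88 ± 0.32, adjusted p = 0.01, measured on 3 of 4 siSix1&4 arrays) fell, while Cck (3.49 ± 0.46, adjusted p = 0.0024, measured on 2 of 4 siSix4 arrays) and the natural killer receptor Klrb1a (2.17 ± 0.33, adjusted p = 0.0047, measured on 3 of 4 siSix4 arrays) rose. None of 44 sarcomere genes passed, and 7 fell adjusted over the list alone (mean -1.38, adjusted p = 0.079 with an estimated correlation). With the slide block 19 fell and that p was 0.039, against 5 and 0.07 with the replicate block, and within slides 1, 2, 3 and 5 the mean was -1.17, -1.51, -1.63 and -1.21. The dystrophin-complex, progenitor and adipocyte lists had means of -0.31, -0.32 and -0.96, and their calls hold with an estimated correlation (adjusted p of 0.021, 0.038 and 0.0072, and of 0.035, 0.035 and 0.035 with the slide block). In all 50 genes changed, 32 higher and 18 lower (the series matrix gave 9 higher and 3 lower), against 255 with the slide block and 138 with the replicate block. The count was 6 under normexp, 19 with no filter, 26 with a filter on all arrays, 12 from the series matrix and 2890 with array weights, and 30, 29 and 25 without siSix4 replicates 1, 2 and 3, and 18 and 24 without siSix1&4 replicates 1 and 3.

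The single knockdowns were compared directly, siSix1 against siSix4, which again includes the array labelled siSix1 replicate 4. Lpl (-2.83 ± 0.22, 7.12-fold, adjusted p = 1.3e-06), Scara5 (-3.36 ± 0.40, adjusted p = 4.9e-04, measured on 1 of 4 siSix1 arrays) and Cxcl13 (-4.39 ± 0.74, adjusted p = 0.0054, measured on 1 of 4 siSix1 arrays) were lower in siSix1. Cck (2.92 ± 0.46, adjusted p = 0.0032, measured on 2 of 4 siSix4 arrays), the cornified envelope gene Sprr1a (2.65 ± 0.37, adjusted p = 0.0011) and Bhlhe40 (1.03 ± 0.21, adjusted p = 0.022) were higher. Lower in siSix1 were also Sgcg, Sgca, Heyl, Igf1 and the p53 targets Zmat3 and Gdf15 (-1.25, -0.76, -1.80, -1.05, -1.0 and -1.67). Six1 differed by -1.59 ± 0.30, adjusted p = 0.013. The 31 mitosis genes were lower as a list (mean -0.57, SD 0.17, none called, 7 fell adjusted over the list alone). That call holds with an estimated correlation (adjusted p = 0.022), as do those of the adipocyte (0.0068), dystrophin-complex (0.039) and progenitor (0.039) lists. These became 0.044, 0.038, 0.063 and 0.038 with the slide block and 0.035, 0.035, 0.068 and 0.052 with the replicate block, in the same order. Both blocks ended the dystrophin-complex call and the replicate block the progenitor call. Within slides 1, 2, 3 and 5 the mitosis mean was -0.84, -0.50, -0.74 and -0.20. None of 44 sarcomere genes passed (mean -0.99, adjusted p = 0.35 with an estimated correlation), and 10 fell with the slide block. In all 136 genes changed, 71 higher and 65 lower, against 564 with the slide block and 365 with the replicate block. With the latter 1 sarcomere and 2 mitosis genes were lower. The count was 74 scaled to each array's median, 17 under normexp, 50 with no filter, 59 from the series matrix, 36 from only the arrays compared and 6364 with array weights, and 89 and 56 without siSix1 replicates 1 and 3, 277 without the array labelled siSix1 replicate 4, and 61, 58 and 65 without siSix4 replicates 1, 2 and 3.

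**Figure D4:**
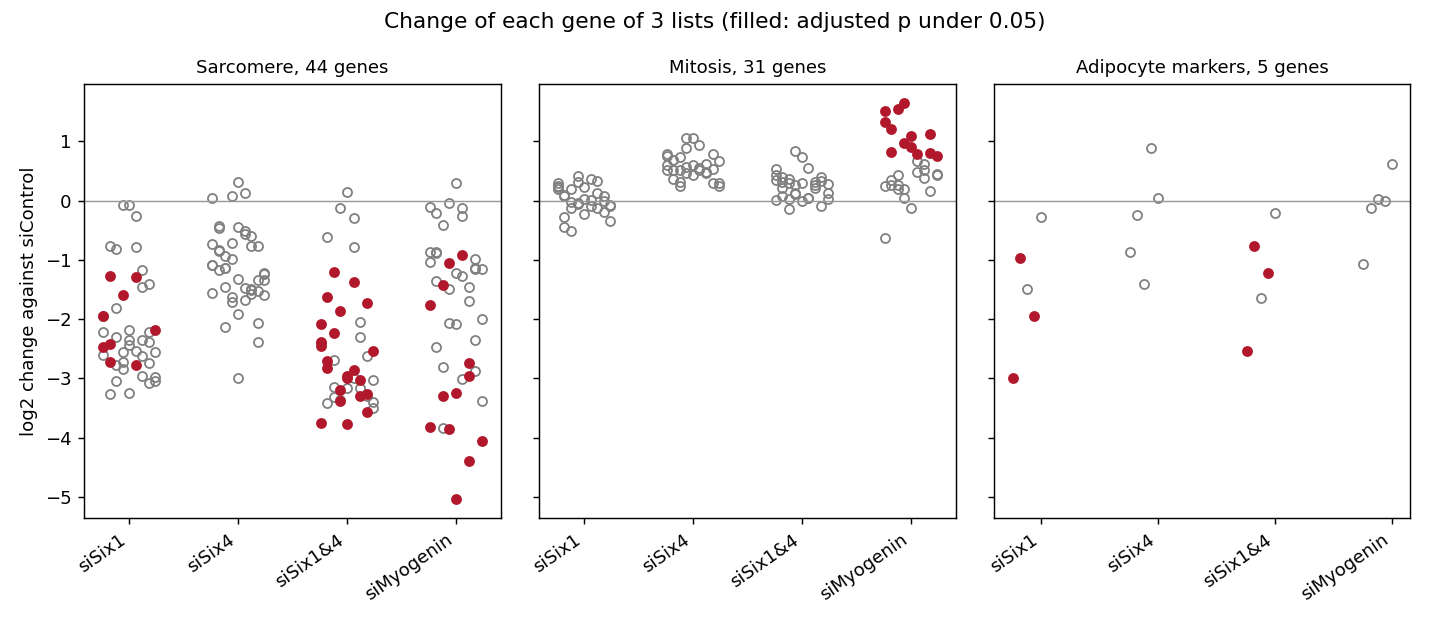
Log2 change against siControl of each measured gene of the sarcomere, mitosis and adipocyte lists, filled where the adjusted p was under 0.05. Most sarcomere genes lie below 0 in every knockdown, and the 13 mitosis genes that passed are in siMyogenin.

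Whether the double knockdown departs from the sum of the single ones was asked as an interaction. Myog (1.1 ± 0.97), Myod1 (0.83 ± 0.36), Six1 (-0.16 ± 0.42) and Six4 (0.82 ± 0.62) did not pass (all adjusted p = 1). The 44 sarcomere and 18 excitation-contraction genes had means of 0.74 and 1.0, with none called (adjusted p = 0.74 and 0.32 with an estimated correlation). limma called 0 genes without a block, with 726 at an unadjusted p under 0.05. Under the slide block 4 passed: Arhgap6, Cd55, Cyb561 and Prr9 (-2.30, 1.93, -1.44 and 2.47, adjusted p of 0.028, 0.047, 0.038 and 0.028). There 1288 had an unadjusted p under 0.05. With the replicate block 5 passed: Arhgap6, Cyb561, Gsta2, Plagl1 and Prr9 (-2.40, -1.38, 3.30, 2.79 and 2.65). Their adjusted p were 0.017, 0.041, 0.031, 0.041 and 0.041, and 1270 had an unadjusted p under 0.05. These genes were chosen after their values were seen. Arhgap6 stood at 3.46, 2.73 and 3.79 and Plagl1 at -2.9, -3 and -3.12 in siSix1, siSix4 and siSix1&4. Prr9 was measured on no siSix4 array, Gsta2 on 3 of 4 and Arhgap6 on 2 of 4 siControl arrays. Low signal may shape these values. Array weights called 1357 genes, slides 1 to 3 alone 35 and with the slide block 783, and slide as a random block 10. The array labelled siSix1 replicate 4 enters these values, and 1 gene passed without it, as also without siControl replicate 3 or siSix1&4 replicate 2.

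How the loss of both Six1 and Six4 differs from the loss of Myogenin was asked by setting siSix1&4 against siMyogenin. The neuronal genes Nefl, a neurofilament (4.73 ± 1.02, adjusted p = 0.01, measured on 3 of 4 siMyogenin arrays), and Gap43, of growth cones (3.10 ± 0.67, adjusted p = 0.011, measured on 2 of 4 siMyogenin arrays), were higher in siSix1&4, as were Klrb1a (3.84 ± 0.33, adjusted p = 9.7e-06, measured on 1 of 4 siMyogenin arrays) and Cxcr6 (3.78 ± 0.38, adjusted p = 4.2e-05, measured on 2 of 4 siMyogenin arrays). Sucnr1 (-4.99 ± 0.62, adjusted p = 1.3e-04, measured on 2 of 4 siSix1&4 arrays), Csta2 (-4.30 ± 0.50, adjusted p = 9.8e-05), Cxcl5 (-2.87 ± 0.32, adjusted p = 8.7e-05, measured on 3 of 4 siSix1&4 arrays), Igf1 (-1.87 ± 0.24, adjusted p = 1.3e-04) and Sgcg (-1.90 ± 0.27, adjusted p = 4.7e-04) were lower. Of 44 sarcomere genes 5 were lower and none higher, including Tnnt1 (-1.42 ± 0.28, adjusted p = 0.0052). Their mean was -0.63 (adjusted p = 0.67 with an estimated correlation), -1.07 with the slide block and -1.57 on slide 5. Of 34 DNA replication genes 2 were lower (mean -0.49, adjusted p = 0.52 with an estimated correlation). Myog differed by -0.28 ± 0.68, adjusted p = 0.8, and Six1 was lower (-1.91 ± 0.30, adjusted p = 9.2e-04). In all 1126 genes changed, 551 higher and 575 lower, against 250 with the slide block and 3101 with the replicate block. With the latter 13 sarcomere and 13 DNA replication genes were lower, and Myod1 passed (-0.70, adjusted p = 0.017). Scaling to each array's median gave 275 higher and 1043 lower, and the series matrix 159 higher and 372 lower. The count was 140 under normexp, 400 with no filter, 233 from only the arrays compared and 6559 with array weights, and 458, 481, 388 and 2225 without siSix1&4 replicates 1, 2, 3 and 4, and 1840 and 491 without siMyogenin replicates 1 and 2.

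The genes changed in more than 1 knockdown were counted against the shared controls. Sgcg fell in siSix1 and siSix1&4, while Cdkn1c fell and Arhgap6 rose in all 4 knockdowns without a block. Tead4 fell in siSix1&4 and siMyogenin, and Zmat3 rose in siSix4 and siMyogenin. The pairs were siSix1 with siSix4, siSix1 with siSix1&4, siSix4 with siSix1&4, siSix1 with siMyogenin, siSix4 with siMyogenin, and siSix1&4 with siMyogenin. In this order 17, 262, 26, 83, 21 and 108 genes were higher and 34, 338, 35, 142, 27 and 170 lower in both, and 0, 0, 0, 15, 0 and 8 changed in opposite directions. Independent lists would share 0.8, 8.5, 0.7, 23.9, 1.9 and 21.9 higher and 1.1, 12.1, 1.1, 18.6, 1.8 and 19.3 lower. In 100 simulations of unchanged groups against the same controls 0 genes were shared. In 100 with slide shifts on the real slides 0 were, and at most 1 with slides blocked. Unchanged groups yield few calls, so these counts cannot show how many shared calls the common controls add. With the controls split 2 and 2 the shared genes numbered 1 to 7, 83 to 103, 1 to 8, 3 to 32, 0 to 5 and 3 to 31. With slides blocked, 312, 1093, 352, 134, 109 and 152 were shared in the same direction.

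Across genes, which are not independent, the changes of these pairs correlated at 0.74, 0.90, 0.80, 0.36, 0.51 and 0.47 in the same order, where simulations of unchanged groups gave 0.50. Simulations on the real slides with slide shifts gave 0.55, 0.55, 0.55, 0.34, 0.34 and 0.34. The covariances were 0.165, 0.261, 0.176, 0.129, 0.137 and 0.164, against 0.053 in the first simulations and 0.044, 0.044, 0.044, 0.031, 0.032 and 0.032 in the second. With the controls split the correlations were 0.40 to 0.56, 0.63 to 0.73, 0.49 to 0.56, 0.01 to 0.56, 0.07 to 0.67 and 0.11 to 0.64, and the mean covariances 0.127, 0.224, 0.138, 0.091, 0.099 and 0.126. With the slide block the correlations were 0.69, 0.88, 0.75, 0.41, 0.57 and 0.57, against 0.55, 0.54, 0.54, 0.30, 0.30 and 0.30 in the second simulations. The array labelled siSix1 replicate 4 enters each value for siSix1.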

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

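The tests on replicate 4, on the array labelled siSix1 replicate 4 and on the siMyogenin count were chosen after the results were seen. Each array was compared with the other 3 of its group, and those listed here lay far from them. Of 500 groups tested 22 were so marked, where chance marks about 1 group in 20.

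Myh1, a fast myosin heavy chain, was low on siSix4 replicate 4 at -0.07 (others 3.72 to 4.35). On the same slide 5 the p53 targets were high on the array labelled siSix1 replicate 4 at 0.75 (others -0.32 to -0.17) and on siSix1&4 replicate 4 at 0.46 (others -0.08 to 0). The extracellular matrix list was low on the array labelled siSix1 replicate 4 at -0.75 (others 0.23 to 0.28) and on siSix1&4 replicate 4 at -0.35 (others 0.13 to 0.20), and on slide 4 it was low on siControl replicate 4 at -0.19 (others 0.04 to 0.08). The dystrophin-complex list was low on siSix4 replicate 4 at -0.35 (others -0.19 to -0.17). The list of Eya, Pax7 and Six5 genes was low on the array labelled siSix1 replicate 4 at -0.79 (others 0.04 to 0.21), as was Six4 at -2.47 (others -0.34 to -0.05).

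Other values on slide 5 were Slc44a4, a choline transporter, on siSix4 replicate 4 at -6.75 (others -4.27 to -3.96), and the keratin Krt31 there at -7.27 (others -5.33 to -5.22). The lectin Colec10 stood at -7.14 (others -3.80 to -3.22) on the array labelled siSix1 replicate 4 and at -4.30 (others -2.80 to -2.49) on siSix1&4 replicate 4. On the array labelled siSix1 replicate 4 Fam110c stood at -3.53 (others -4.64 to -4.46) and Speer3 at 0.14 (others -3.19 to -2.88). On other slides Krt31 stood at -7.89 (others -6.02 to -5.76) on siSix1 replicate 3, Lgr5 at -7.83 (others -4.25 to -3.85) on siMyogenin replicate 2, and Cyb561 at -1.21 (others -1.74 to -1.65) on siMyogenin replicate 3. Pvalb stood at -4.73 (others -4.04 to -4.03) on siControl replicate 2 and Csta2 at -3.05 (others -3.53 to -3.48) on siControl replicate 3. The osteoblast and chondrocyte list stood at -0.05 (others 0.16 to 0.17) on siSix1&4 replicate 3, and the median background signal at 28.5 (others 16 to 17.5) on siSix1&4 replicate 1.

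The sarcomere genes were lowest on replicate 4 of siSix1, siSix4 and siSix1&4, at -1.01, -2.09 and -1.67 relative to the lowest other replicate. Low signal stays open. For siSix4 and siSix1&4 the 75th percentile was at least 0.90 of the lowest other. The median signal was 31.5 and 27.9, below the lowest other of 39.8 and 40.8. For siSix1, dim siMyogenin replicates 2 and 3 had a sarcomere level higher by 1.36 than 1 and 4, but Myog was higher too, by 1.63. A deeper loss of Six1 was not seen, with Six1 higher on replicate 4 by 0.72 in siSix1&4 and 1.46 in siSix1. Six4 and Myog were lowest there in these and in siSix4, so their deeper loss stays open. So does a shift of slide 5 or its cultures: siMyogenin replicate 4 was lowest of its group too, at -0.12 from the next. Slide 5 held no control, so slide and culture effects could not be separated.

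Six1 stood near the control level on the array labelled siSix1 replicate 4. Over 144 genes that differed by at least 2-fold between siSix1 and siControl on slides 1 to 3 and little between siSix4 and siControl, the siSix1 minus siSix4 difference on slide 5 had a slope of 0.56 ± 0.06 (SE across genes, which are not independent) on that of slides 1 to 3. A label exchange with siSix4 replicate 4 needs a slope below 0, a culture without siRNA effect one near 0. The slope argues against both, but low signal stays open and may bias it. Of its fall on replicates 1 to 3 Six1 kept a share of 0.11 on that array, and 28 genes of similar level outside the lists a median share of 0.71 (quartiles 0.07 to 1.38). With list members, many of them muscle genes, it was 1.15 over 52 genes (quartiles 0.67 to 2.04). A smaller loss of Six1 at harvest was not tested.

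The siMyogenin count fell from 1724 to 231 with the slide block. Over the 1724 genes, siControl replicate 4, which shared a slide with siMyogenin replicates 1 to 3, lay toward siMyogenin from the other controls by a median of 0.43 (quartiles 0.16 to 0.71), against a median change of 1.03. For siControl replicates 1 to 3 that median was -0.14, -0.31 and 0.01. A slide 4 shift may account for part of these calls, but siControl replicate 4, the only control there, had the lowest control signal. The change on siMyogenin replicate 4, on slide 5, was 0.93, within the 0.77 to 1.33 of the others. Without the dim siMyogenin replicates 2 and 3 the count went from 412 to 676 (1.64 times) and so did not fall. It went from 1223 to 922, 161 to 612, 3423 to 680, 209 to 162 and 111 to 162 without replicates 1 and 2, 1 and 3, 1 and 4, 2 and 4, and 3 and 4. The fall ended without other pairs too, so low signal stays open beside a slide shift. A biological difference of that control culture was not tested, nor was precision lost to the block, with 1 control on slides 4 and 5. The tests first planned were dropped, since the choice of their genes bore on the outcome.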

How the results depend on the processing

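The slide as a random block, slides 1 to 3 alone or with a block, and the fit without the array labelled siSix1 replicate 4 and siMyogenin replicate 3 were chosen after the data were seen. The number of changed genes depended on the setting more than the directions did. Of the alternatives' values 6844 kept direction and side of the threshold, 1691 no longer passed, 71 newly passed, 176 counts moved by more than 1.5 times and 70 changed sign, most of the last for genes that did not pass. Depth limits the dim arrays: the 75th percentile signal was 96.6 on siMyogenin replicate 3. All settings set out beforehand were run, but camera gives no result for a random block, so the lists have none. Among named genes the replicate block ended 0 calls. Against siControl it made Myog, Myf6 and Mef2c pass in siSix1, Six4 and Eya1 in siSix4, Mef2c and Eya1 in siSix1&4, and Six1 and Mef2c in siMyogenin. It also made Myod1 and Myf6 pass in siSix1 against siSix4 and Myod1 in siSix1&4 against siMyogenin. Among lists at the preset correlation (new adjusted p in brackets) it made those of regulators (0.044) and neural genes (0.044) pass in siSix4, and the neural list in siSix1&4 against siSix1 (0.0089) and siSix1 against siSix4 (0.014). It did so for the inflammatory list in siSix1&4 against siMyogenin (0.043) and for slow-fibre (0.019) and embryonic genes (0.017) in the interaction, and ended that of the dystrophin complex in siMyogenin (0.058). With an estimated correlation it ended 5 list calls in siSix1, most in siSix1&4 and 2 in siSix1 against siSix4, each printed in the report, and it changed no other camera call or call of a named gene. Not in the report are these list counts, which it moved by more than 1.5 times and by over 2 genes. In siSix1 it gave as lower 3 matrix (from 0) and 4 progenitor (from 1) genes, and as higher 4 cytoskeletal (from 0) genes, in siSix1&4 as higher 3 matrix (from 0) genes, in siSix1&4 against siSix4 as lower 4 inflammatory (from 1) genes and in siSix1 against siSix4 as lower 6 inflammatory (from 3) genes. In siMyogenin, whose numbers do not pair with siControl, it gave as lower 5 regulator (from 2), 29 sarcomere (from 13), 10 fast-fibre (from 4), 5 slow-fibre (from 1), 7 embryonic and cardiac (from 3), 10 excitation-contraction (from 2), 7 metabolism (from 3), 5 unfolded-protein (from 1) and 4 neural (from 1) genes, and as higher 3 Notch (from 0) and 7 cholesterol (from 4) genes, and in siSix1&4 against siMyogenin as lower 5 fast-fibre (from 1), 5 excitation-contraction (from 2), 4 junction (from 1), 7 mitosis (from 1), 6 cholesterol (from 1) and 5 oxidative phosphorylation (from 0) genes. Other list counts moved by at most 2 genes or by less than 1.5 times. For Six1 in siSix1 the changes under the alternatives were -1.69 to -1.04, at adjusted p of 3.2e-07 to 0.12. In the values below the cause was not tested.

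Under quantile normalization, changed genes numbered 227 for siSix4. Shared genes then numbered 164 for siSix1 with siSix4, 184 for siSix4 with siSix1&4 and 127 for siSix4 with siMyogenin. Scaled to each array's median, the changes were -1.30 for Six1 in siSix1, -1.11 for Six1 in siSix1&4, and 0.15 and 0.14 for Myf5 and Six5 in siMyogenin. Changed genes then numbered 74 for siSix1 against siSix4. Under normexp, changed genes numbered 163 for siSix1, 6 for siSix4, 243 for siSix1&4, 75 for siMyogenin, 6 for siSix1&4 against siSix4, 17 for siSix1 against siSix4 and 140 for siSix1&4 against siMyogenin. The changes then were 0.15, 0.34, 0.01, 0.04 and 0.09 for Six4, Myf6, Eya3, Eya4 and Saa3 in siSix1, 0.14, -2.98, 1.27, 1.19, 0.43, 0.07, 0.53 and 0.76 for Cfap52, Myog, Myf5, Myf6, Mef2c, Six5, Adam12 and Lum in siMyogenin, and 0.15 for Cd36 in siSix1 against siSix4. Genes shared came to 4, 104, 6, 15, 1 and 20 for siSix1 with siSix4, siSix1 with siSix1&4, siSix4 with siSix1&4, siSix1 with siMyogenin, siSix4 with siMyogenin and siSix1&4 with siMyogenin, the order of the 6 pairs below. Without a filter, changed genes numbered 366 for siSix1, 16 for siSix4, 350 for siSix1&4, 158 for siMyogenin, 19 for siSix1&4 against siSix4, 50 for siSix1 against siSix4 and 400 for siSix1&4 against siMyogenin. Single changes became -1.27 for Six1 in siSix1, -1.11 for Six1 in siSix1&4, and -2.56 for Myog in siMyogenin. The genes shared numbered 12, 253, 11, 32, 6 and 34 for the 6 pairs. Filtering on all arrays, changed genes numbered 26 for siSix1&4 against siSix4. Taking the mean of a gene's probes, the changes were -1.02 and 0.04 for Six1 and Eya3 in siSix1&4, and -0.08 for Col5a1 in siMyogenin. From the series matrix, changed genes numbered 491 for siSix1, 31 for siSix4, 717 for siMyogenin, 12 for siSix1&4 against siSix4, 59 for siSix1 against siSix4 and 531 for siSix1&4 against siMyogenin. Log2 changes were then 0.10 and 0.10 for Eya3 and Eya4 in siSix1, 0.03 and 0.02 for Myf6 and Eya4 in siSix4, 0.02 and 0.15 for Eya3 and Eya4 in siSix1&4, 0.47, 0.26, 0.25 and 0.05 for Myf5, Myf6, Eya3 and Eya4 in siMyogenin, and 0.21 for Bub1 in siSix1&4 against siMyogenin. Fitting only the arrays compared, changed genes numbered 524 for siSix1, 256 for siSix4, 718 for siMyogenin, 36 for siSix1 against siSix4 and 233 for siSix1&4 against siMyogenin. Values of genes were -1.27 for Six1 in siSix1, and -1.21 for Six4 in siSix4. Array weights ran from 0.081 to 16, so counts under them rest largely on few arrays. Under array weights, changed genes numbered 4987 for siSix1, 4697 for siSix4, 3695 for siSix1&4, 6493 for siMyogenin, 5 for siSix1&4 against siSix1, 2890 for siSix1&4 against siSix4, 6364 for siSix1 against siSix4, 6559 for siSix1&4 against siMyogenin and 1357 for the interaction. The changes then were 0.22, -0.20, 0.05 and 0.08 for Six4, Myf5, Eya3 and Eya4 in siSix1, -1.06 and 0.02 for Six4 and Mef2c in siSix4, 0.04 for Eya3 in siSix1&4, and 0.04 for Myf5 in siMyogenin. Under the replicate block, changed genes numbered 1583 for siSix1, 483 for siSix4, 1427 for siSix1&4, 4232 for siMyogenin, 138 for siSix1&4 against siSix4, 365 for siSix1 against siSix4, 3101 for siSix1&4 against siMyogenin and 5 for the interaction. Single changes became -1.21 for Six4 in siSix4. Shared genes then numbered 336, 1108, 369, 616, 327 and 724 for the 6 pairs. Under the slide block, changed genes numbered 1549 for siSix1, 447 for siSix4, 1451 for siSix1&4, 231 for siMyogenin, 255 for siSix1&4 against siSix4, 564 for siSix1 against siSix4, 250 for siSix1&4 against siMyogenin and 4 for the interaction. Log2 changes were then -0.20 for Myf5 in siSix1, 0.13 for Mef2c in siSix4, and 0.66 and 0.16 for Myf5 and Six5 in siMyogenin. Genes shared came to 312, 1093, 352, 134, 109 and 152 for the 6 pairs. At 2-fold or more, changed genes numbered 513 for siSix1, 537 for siSix1&4, 908 for siMyogenin and 681 for siSix1&4 against siMyogenin. The genes shared numbered 398 for siSix1 with siSix1&4, 128 for siSix1 with siMyogenin, 30 for siSix4 with siMyogenin and 159 for siSix1&4 with siMyogenin. Under camera with an estimated correlation, called lists numbered 5 for siSix1, 0 for siSix4, 7 for siSix1&4 and 0 for siMyogenin. Under fry, called lists numbered 2 for siSix4 and 6 for siMyogenin. Treating the slide as a random block, changed genes numbered 1481 for siSix1, 370 for siSix4, 1300 for siSix1&4, 761 for siMyogenin, 152 for siSix1&4 against siSix4, 436 for siSix1 against siSix4, 521 for siSix1&4 against siMyogenin and 10 for the interaction. Values of genes were 0.18 and 0.04 for Myf5 and Six5 in siMyogenin. Leaving out the array labelled siSix1 replicate 4 and siMyogenin replicate 3, the changes were 0.22, 0.07 and 0.22 for Six4, Eya3 and Eya4 in siSix1, -1.21 for Six4 in siSix4, and 0.07 for Myf5 in siMyogenin. The changed genes came to 636 for siSix4, 1722 for siSix1&4, 131 for siSix1&4 against siSix4, 622 for siSix1 against siSix4, 1792 for siSix1&4 against siMyogenin and 2 for the interaction. On slides 1 to 3 only, changed genes numbered 2355 for siSix1, 1532 for siSix4, 2403 for siSix1&4, 643 for siSix1&4 against siSix4, 2212 for siSix1 against siSix4 and 35 for the interaction. The changes then were 0.20, -0.15, 0.10 and 0.04 for Six4, Myf5, Eya3 and Eya4 in siSix1, and -1.02 and 0.16 for Six4 and Mef2c in siSix4. On slides 1 to 3 with the slide block, changed genes numbered 5100 for siSix1, 4938 for siSix4, 5281 for siSix1&4, 34 for siSix1&4 against siSix1, 2898 for siSix1&4 against siSix4, 6193 for siSix1 against siSix4 and 783 for the interaction. Single changes in siSix1 and siSix4 were the same, with -0.53 for Six4 in siSix1&4. Over splits of the controls 2 and 2 the shared genes numbered 1 to 7, 83 to 103, 1 to 8, 3 to 32, 0 to 5 and 3 to 31 for the 6 pairs.

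Leaving out each array in turn, changed genes numbered 431 to 844 for siSix1, 16 to 43 for siSix4, 403 to 660 for siSix1&4, 200 to 2998 for siMyogenin, 0 to 1 for the interaction, 56 to 277 for siSix1 against siSix4, 18 to 58 for siSix1&4 against siSix4 and 388 to 2225 for siSix1&4 against siMyogenin, and the ranges of single values were -1.63 to -1.04 for Six1 in siSix1, -0.59 to 0.22 for Six4 in siSix1, -0.01 to 0.31 for Six5 in siSix1, -0.37 to 0.07 for Eya3 in siSix1, -0.49 to 0.22 for Eya4 in siSix1, -1.1 to 0.21 for Mef2c in siSix4, -0.25 to 0.02 for Six5 in siSix4, -1.29 to -0.96 for Six1 in siSix1&4, -0.07 to 0.21 for Six5 in siSix1&4, -2.86 to -2.18 for Myog in siMyogenin, -0.83 to 0.58 for Myf5 in siMyogenin and -0.25 to 0.07 for Six5 in siMyogenin.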

Other observations

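The counts of other splits were all chosen after the results were seen, and the tests of imprinted genes were written before. Of 7 neural markers the neurofilament Nefl fell in siMyogenin (-3.71 ± 1.02, adjusted p = 0.031, measured on 3 of 4 siMyogenin arrays), also with the slide block (-2.18, adjusted p = 0.0039). In siSix4 the list had a mean of 0.38 with none called without a block (adjusted p = 0.71 with an estimated correlation). Blocking by slide, 3 rose and the mean was 0.70 (adjusted p = 0.048 with an estimated correlation): Nefl (1.76, adjusted p = 0.0044), Nefm (1.52, adjusted p = 0.0027) and Stmn2 (0.93, adjusted p = 0.0055). Relative to the control mean the list stood at 0.56, 0.89, 1.01 and -0.93 on siSix4 replicates 1 to 4 and at 0.51, 0.81, 0.91 and -0.98 on siSix1&4, so replicate 4, on slide 5, went the other way. The other arrays of slide 5 were low too, at -1.33 on the array labelled siSix1 replicate 4 and -2.49 on siMyogenin replicate 4. In siSix1&4 the slide-block mean was 0.63 and Nefl rose (1.64, adjusted p = 0.0015), as did Gap43 (1.23, adjusted p = 0.018) and Stmn2 (0.55, adjusted p = 0.035). Against siMyogenin the siSix1&4 list mean was 1.82 (adjusted p = 0.52 with an estimated correlation), and 1.46 with the slide block (adjusted p = 0.0023). The replicate block gave the list adjusted p of 0.25, 0.51 and 0.18 in siSix4, siSix1&4 and this comparison.

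Plagl1, Igf2 and Cdkn1c are imprinted genes of fetal growth. Plagl1 stood at -2.90, -3.00 and -3.12 in siSix1, siSix4 and siSix1&4, and at -0.17 in siMyogenin, where it did not pass. Igf2 stood at -3.15, -1.95, -3.23 and -1.27 in the same order (not passed in siSix4 and siMyogenin), and Cdkn1c at -1.79, -2.19, -2.30 and -1.46. The hypothesis that imprinted genes fall as a set was tested on 20 others with camera and an estimated correlation. In siSix1 their mean was -0.22 (SD 0.62, adjusted p = 0.16), with Gatm (-1.59) and Usp29 (-1.21) lower. In siSix1&4 it was -0.20 (adjusted p = 0.26), with Gatm lower (-1.99), so the hypothesis stays undecided in these 2. The bound on the mean was first set at 0.25 and then made to include its standard error after the values were seen, and by the first form both would count against the hypothesis. In siSix4 (mean -0.03, adjusted p = 0.92) and siMyogenin (mean -0.03, adjusted p = 0.79) no fall of the set was seen.

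The arrays compared were also split into groups in all 35 ways that give 2 groups of 4. For siSix1, siSix4 and siSix1&4 against siControl 1 of 35 splits, the real one, gave as many genes (842, 74 and 824, the highest other 0). Same-numbered arrays pair, so only the 8 splits that part every pair are a fair test. There the real one alone gave as many, the others 0, but 8 are too few for a share under 0.05. The same held for siSix1&4 against siSix4 (50, 1 of 35) and siSix1 against siSix4 (136, 1 of 35), with 0 in every other split. For siMyogenin 1 of 35 gave as many as 1724, and the highest other, 761, set siControl replicates 1 to 3 with siMyogenin replicate 3 apart and partly follows the slides. The blocked count was 231. For siSix1&4 against siMyogenin 2 of 35 gave as many as 1126, the other being 1462 with siSix1&4 replicates 1 to 3 and siMyogenin replicate 3 set apart, so chance cannot be excluded. That split follows the slides in part and parts 2 of the 4 pairs, and the slide-block count was 250. Of the 8 splits that part every pair the real one gave 1126 and the others 0, and 8 are again too few. For siSix1&4 against siSix1 all 35 gave as many as 0, and for the interaction all 100 drawn splits, with a highest of 3. For called lists 4 of 35 splits gave as many as 13 in siSix1 (highest other 13), 4 gave as many as 12 in siSix4 (15) and 8 gave as many as 13 in siSix1&4 (15), so chance cannot be excluded for these counts. In siMyogenin 1 of 35 gave as many as 13 (highest other 11).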
